A study of Mus musculus with 2 samples.

How the data were processed

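Single-cell RNA-seq was measured in 2 libraries from the mouse colon (proximal and distal colon and rectum, C57BL/6), 1 from DSS-treated wild-type mice and 1 from DSS-treated mice labelled Elf1 knockout, each pooling cells of 3 mice. Cells were captured on Singleron GEXSCOPE microchips with barcodes and UMIs and sequenced on Illumina NovaSeq. The submitters name cutadapt 1.17, STAR 2.6.1a and featureCounts 2.0.1 with the GRCm38 genome. The deposited values are counts, raw UMIs per gene and barcode with no normalization by the authors. The lowest total of a barcode was 500 UMIs in both. The wild-type file lists 26425 genes and the other 25467, of which 23197 are in both, and genes listed in both hold 99.947% of all UMIs. DSS dose, days of treatment, colitis severity and the deleted part of Elf1 are not given in the sources used here.

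Barcodes were kept with at least 500 UMIs, at least 200 genes and at most 25% mitochondrial UMIs. The limits removed 117 and 239 barcodes under 200 genes and 438 and 83 over 25% mitochondrial UMIs (wild type and labelled knockout, with overlap possible). Doublets were called by scrublet within scanpy 1.11.5 in each library with an expected rate of 0.06. The caller marked 2.347% of the library labelled knockout, or 235 barcodes. It marked 0.012% of the wild-type library, so that the 5% of barcodes passing these limits with the highest scores, 404, were removed there, by the rule fixed for a share under 0.5%. This left 7729 and 9504 cells with 30096863 and 37513953 UMIs. Both libraries were clustered together (counts per 10000, log1p, 2000 variable genes chosen within libraries, 30 principal components, 15 neighbours, Leiden resolution 1.0 in igraph 0.11.9), with sex-linked, mitochondrial, ribosomal, haemoglobin and immunoglobulin genes left out of the variable genes. Clusters were named from lists of marker genes. The naming rule was set after the clusters had been seen: a class needed at least 3 markers among a cluster's 50 leading genes, the most of any class, and at least 1 among the leading 10, not fewer than any other class. Leading genes were ranked by fold over all other cells. One cluster, 15, stayed unnamed, with 0.311% and 1.74% of cells (24 and 165 cells, at medians of 607.5 and 743 UMIs). T cells, macrophages and epithelial cells were clustered again to name subtypes, which needed 2 of the leading 10 genes and more than any other subtype.

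Most fibroblasts lay in cluster 9 (70.2%) in the wild-type library and in clusters 17 (42.0%) and 24 (38.3%) in the other, B cells in clusters 3 (46.7%) and 2 (41.3%) against 2 (91.2%), smooth muscle cells in 11 (70.2%) against 16 (79.4%) and epithelial cells in 7 (84.5%) against 12 (81.4%). T cells lay mostly in clusters 4 (52.3% against 47.1%), 10 (36.1% against 23.5%) and 6 (9.32% against 24.6%), macrophages in 0 and 1 and endothelial cells in 22 and 27, and plasma cells, neutrophils and dendritic cells each formed 1 cluster.

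Shares of cells carry exact Clopper-Pearson intervals, except that a share of 0 carries as its limit the share that 3 cells would make. Expression within a class is the sum of UMIs over its cells, as CPM with exact Poisson intervals, and ratios of labelled knockout over wild type carry exact conditional binomial intervals, all at 95% and for counting error only (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, python 3.11.15). With 1 library per group and no map from cells to mice, no test, p-value or count of changed genes was made. A count of 0 was taken as 3 and gives a bound. Classes with at least 100 cells in each library were compared. Named genes were the 12 highest and 12 lowest ratios in the 3 largest classes (fibroblasts, B and T cells) and the 4 highest and 4 lowest in the others. They needed listing in both files, at least 50 UMIs in the class, a UMI in at least 10% of cells of 1 library and an interval of the ratio that excluded 1. Mitochondrial, ribosomal, haemoglobin, immunoglobulin variable, T cell receptor variable and joining and sex-linked genes, gene models and markers of other classes were left out. Of the genes these rules select, 1 in fibroblasts, and of the extreme list members 2, are not reported here. Lists of genes were described by the median log2 ratio of members with at least 50 UMIs, beside 10000 random lists matched on mean expression in 20 bins. In each class the 4 lists of at least 8 members farthest from the middle of their random lists were described, with those fixed for the class. The filters, markers, lists and rules for naming genes were set before the data were examined, apart from the naming of clusters and the background bound. That bound is, per gene and library, the lowest mean UMIs per cell among named classes of at least 40 cells. Coordinates are from GENCODE on GRCm38.

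The method was tested for counting error only, on data simulated from these libraries with no spread between mice. Intervals excluded 1 in 3.35% to 4.26% of unaltered genes, and in 37.3% to 79.1% of genes altered 1.5-fold and 90.9% to 100% of those altered 4-fold. Of unaltered lists, 3% to 7% fell outside the 2.5 to 97.5 percentiles of random lists. The alternatives were other limits on mitochondrial UMIs and depth, doublets kept, Leiden resolutions 0.5 and 2.0, clustering of each library alone, shares without epithelial cells or neutrophils, TMM scaling (trimmed mean of M values, edgeR 4.0.16 in R 4.3.3), totals without mitochondrial, haemoglobin and immunoglobulin genes, equal weight for each cell, cells thinned to 1000 UMIs, and other choices of list members. Others, chosen after seeing the data, subtracted the bound or kept only list members at 3 times the bound or more. Figures were drawn with matplotlib 3.10.9.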

Results

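Single-cell RNA-seq libraries were made from the colon of mice given dextran sulfate sodium (DSS), a polymer that injures the colonic epithelium and is used as a model of colitis. One library came from wild-type mice and 1 from mice labelled Elf1 knockout, each from the pooled cells of 3 C57BL/6 mice. The comparison asks which cell types, genes and gene groups differ between the inflamed colon of mice under these 2 labels. Per the deposited files the wild-type library held 8635 barcodes and 32481613 UMIs (unique molecular identifiers, each counting 1 RNA molecule), and the library labelled knockout 10012 barcodes and 39750319 UMIs. After filtering, 7729 and 9504 cells remained, with medians of 2037 and 2639.5 UMIs and of 929 and 1055 genes per cell. Both libraries had 2 UMIs of the X-inactivation RNA Xist, and 1892 and 2881 UMIs of the Y-linked gene Ddx3y. There were no replicates and no map from cells to mice, so no difference was tested. Values are given as wild type against labelled knockout, and the 95% intervals in parentheses cover counting error only. CPM is the usual scaling of a gene's UMIs to the total UMIs of its class in the library. The background bound of a gene is its lowest mean UMIs per cell among the named classes of a library, the most that free RNA could add if every cell took up the same amount. Genes and list members at 3 times the bound lie at that level or more.

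Elf1, an ETS-family transcription factor (ENSMUSG00000036461, GRCm38 chromosome 14, 79481194 to 79582494, plus strand), is the gene named in the knockout label. Its RNA was present in the library labelled knockout at close to the wild-type level, with 5773 against 6764 UMIs, or 192 (187 to 197) against 180 (176 to 185) CPM over all kept cells, a ratio of 0.940 (0.907 to 0.974). T and innate lymphoid cells had 535 (502 to 569) against 441 (414 to 470) CPM, a ratio of 0.826 (0.755 to 0.904). The level was higher in the library labelled knockout in B cells, at 392 (376 to 409) against 527 (493 to 562) CPM, in smooth muscle cells and pericytes, at 159 (137 to 185) against 233 (217 to 249) CPM, and in fibroblasts, at 133 (123 to 143) against 152 (147 to 159) CPM. In the other 8 of the 12 classes outside the erythroid cells, such as epithelial cells, macrophages and mast cells, the ratio lay between 0.710 and 1.19 with an interval that included 1. At least 1 Elf1 UMI was seen in 54.9% against 51.4% of T cells, at median depths of 1751 and 1482.5 UMIs. Erythroid cells gave 6.82% against 3.61%, at 9058.5 and 6888 UMIs. With each cell thinned to 1000 UMIs these shares were 38.9% against 37.1% of T cells, and 2.27% of erythroid cells against 0 of 83, which allows a share of cells with a UMI of up to 3.61% and sets no limit on cells that express the gene. The deleted part of Elf1 is not given in the sources used here and UMIs were counted over the whole gene, so its level checks nothing about the deletion, and every direction given here follows the labels. TMM scaling turned the log2 ratio of Elf1 over all cells to 0.16, and thinning that in T cells to 0.03.

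**Figure D1:**
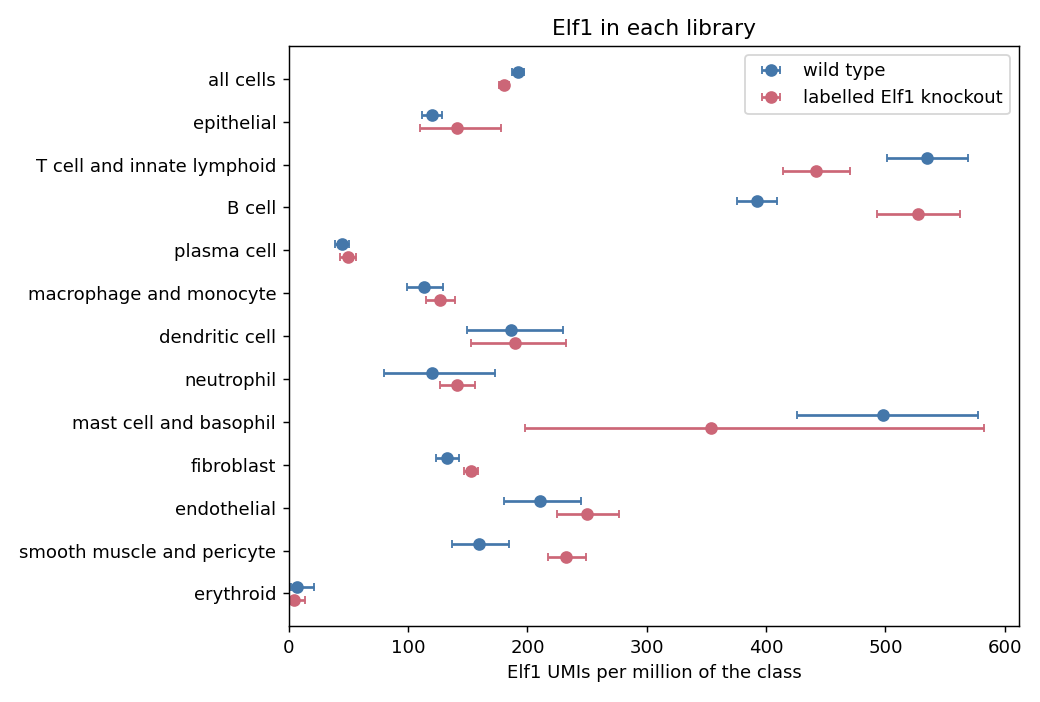
Elf1 level in CPM (UMIs scaled to the class total) in all kept cells and in 12 cell classes, 1 point per library, with 95% exact Poisson intervals as bars. The points of both libraries lie close together in most classes, and the interval in T cells lies lower, and in B cells higher, in the library labelled knockout.

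Among classes, the ratio of shares lay farthest from 1 in the epithelium. Epithelial cells, which line the gut, made up 13.8% (13.04 to 14.6) of kept cells in the wild-type library and 0.737% (0.575 to 0.930) in the library labelled knockout, 1067 against 70 cells, or 18.7-fold (14.7 to 24.2) lower. B cells were 3.07-fold (2.86 to 3.31) lower, at 32.8% (31.8 to 33.9) against 10.7% (10.1 to 11.3), and mast cells and basophils 5.29-fold (3.22 to 9.08) lower, at 1.11% (0.891 to 1.37) against 0.210% (0.129 to 0.325). Neutrophils were 6.28-fold (5.33 to 7.44) higher, at 2.11% (1.80 to 2.45) against 13.2% (12.6 to 13.9). Fibroblasts were 1.83-fold (1.71 to 1.96) higher, at 15.9% (15.1 to 16.7) against 29.1% (28.2 to 30.02). Smooth muscle cells and pericytes were 2.49-fold (2.22 to 2.80) higher, at 5.16% (4.68 to 5.68) against 12.9% (12.2 to 13.6). Macrophages and monocytes were 1.44-fold (1.30 to 1.60) higher, at 7.25% (6.68 to 7.85) against 10.4% (9.83 to 11.1), and endothelial cells 1.30-fold (1.10 to 1.54) higher. T and innate lymphoid cells made up 11.5% (10.8 to 12.3) against 9.97% (9.38 to 10.6), plasma cells 4.15% against 3.54% and dendritic cells 1.73% against 2.06%. Enteric glia and neurons held 0.466% against 0.579% and erythroid cells 0.569% against 0.873%. Shares sum to the whole, so among non-epithelial cells alone B cells held 38.1% against 10.8%, neutrophils 2.45% against 13.3%, fibroblasts 18.5% against 29.3% and T cells 13.4% against 10.0%. The epithelial share ratio was 0.0534, and 0.088 to 0.0987 under the settings that moved it. Epithelial medians of mitochondrial UMIs were 6.90% against 3.07%. A cluster of 539 against 13 epithelial-like cells, unnamed at resolution 2.0, had 11.7%. Resolution 2.0 moved the ratios of smooth muscle to 1.00, macrophages to 2.44 and dendritic cells to 3.47, and separate clustering turned that of glia from 1.24 to 0.747. At resolution 2.0 a cluster of 27 against 751 cells, which shares leading genes with smooth muscle cluster 16, was named fibroblast.

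**Figure D2:**
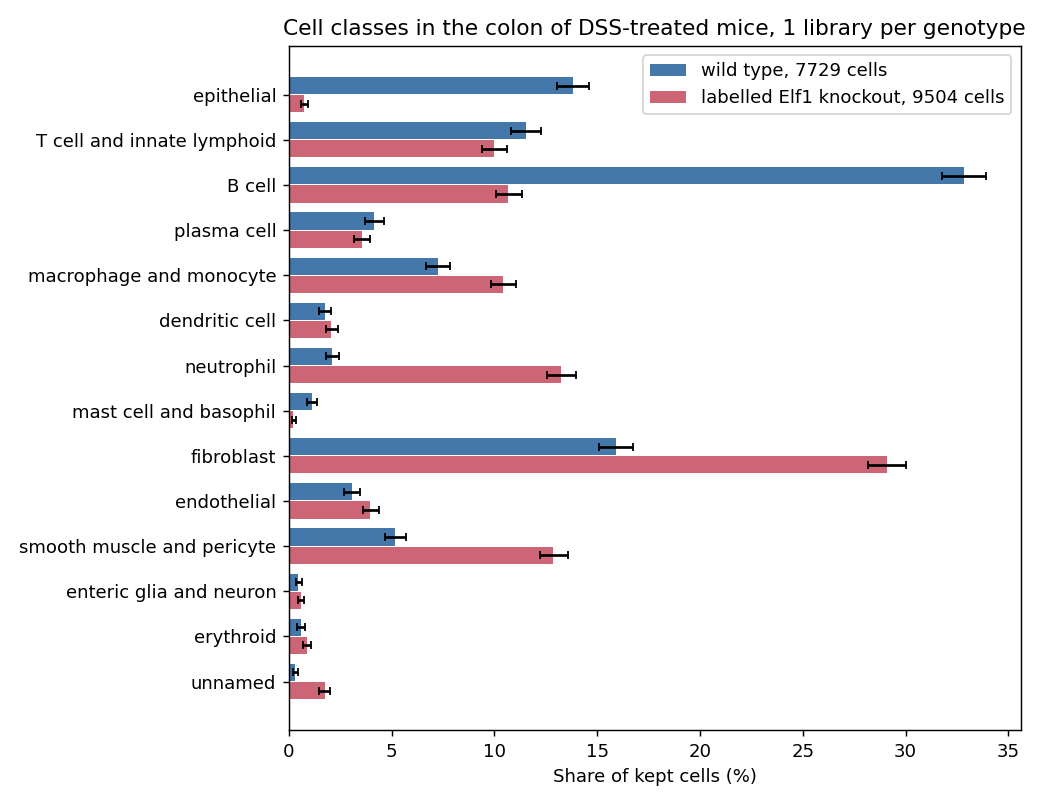
Share of kept cells (%) in 14 classes, 1 bar per library, with 95% exact Clopper-Pearson intervals. Wild type against labelled knockout, epithelial cells stand at 13.8% against 0.737% and neutrophils at 2.11% against 13.2%.

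Subtypes within the T cells, macrophages and epithelium also differed in share. Among T and innate lymphoid cells, the gamma delta sub-cluster held 0.673% (0.248 to 1.46) against 10.7% (8.76 to 12.8), 6 against 101 cells. This was 15.8-fold (7.02 to 44.1) higher. A Trdc UMI was in 4.60% against 12.8% of the class. Regulatory T cells made up 6.06% (4.59 to 7.83) against 13.6% (11.5 to 15.96). CD4 T cells held 44.3% (41.0 to 47.7) against 13.4% (11.3 to 15.7), innate lymphoid and NK cells 13.5% (11.3 to 15.9) against 6.86% (5.33 to 8.66), and CD8 T cells 12.2% against 9.70%. Unnamed T cells held 23.2% against 45.8%. Among macrophages, monocytes and inflammatory macrophages held 5.36% (3.64 to 7.56) against 29.7% (26.9 to 32.7). Resident macrophages held 25.9% (22.3 to 29.7) against 13.1% (11.1 to 15.4). Of the epithelial cells, 182 against 3 were absorptive colonocytes and 121 against 0 mucus-making goblet cells, and 0 of 70 allows a share of up to 4.29%. Undifferentiated and cycling epithelial cells numbered 74 against 0. Enteroendocrine cells numbered 24 against 55, or 2.25% (1.45 to 3.33) against 78.6% (67.1 to 87.5) of the epithelium. Unnamed cells held 62.4% against 17.1% of the epithelium and 68.8% against 57.2% of macrophages. At sub-clustering resolution 0.5, monocytes and inflammatory macrophages held 57.1% against 57.7% of macrophages, a ratio of 1.01, and resident macrophages 42.7% against 38.6%. That setting put CD8 T cells at 31.9% against 19.1%, a ratio of 0.599 (0.494 to 0.724), and unnamed T cells at 13.2% against 46.6%. Of these, 65 against 328 cells formed a sub-cluster nearest CD4 T cells by 3 of 50 leading genes. The lower CD4 share may reflect naming.

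Fibroblasts, the cells that build the connective tissue of the mucosa, carried higher RNA for Csf3, Fabp4, Fth1 and Mt1 in the library labelled knockout, and lower RNA for Wnt2, Wnt4 and Igfbp3. Csf3, the growth factor that drives neutrophil production (ENSMUSG00000038067, chromosome 11, 98701263 to 98703629, plus strand), stood at 134 against 1594 CPM, 11.9-fold (11.1 to 12.8) higher. The fatty acid carrier Fabp4 (ENSMUSG00000062515, chromosome 3, 10204088 to 10208576, minus strand) was 14.2-fold (10.02 to 20.9) higher, at 5.74 against 81.6 CPM, with a UMI in 2.20% against 12.4% of the cells, and is also among the genes that lead endothelial cluster 22. Fth1, the heavy chain of the iron store ferritin, was 6.28-fold (6.203 to 6.36) higher at 4835 against 30361 CPM, and the metallothionein Mt1, which binds zinc and copper, 5.63-fold (5.58 to 5.69) higher at 6849.6 against 38588 CPM. The haemoglobin scavenger Hp was 5.91-fold (5.49 to 6.38) higher, the activin antagonist Fst 5.46-fold (4.49 to 6.70) and the AP-1 subunit Fosl1 4.79-fold (3.71 to 6.27). The other 5 genes at the top were Ampd3 (7.23-fold, 5.01 to 10.8), Sult5a1 (6.50-fold, 5.12 to 8.35), Arl4c (4.79-fold, 3.39 to 6.95), Dpep1 (4.75-fold, 4.37 to 5.18) and Kcne4 (4.60-fold, 3.72 to 5.74). At the other end, 2 Wnt ligands, which act on epithelial stem cells and on the mesenchyme, were lower, Wnt2 (ENSMUSG00000010797, chromosome 6, 17988940 to 18030585, minus strand) 17.9-fold (12.4 to 26.5) at 37.3 against 2.09 CPM and Wnt4 (ENSMUSG00000036856, chromosome 4, 137277489 to 137299726, plus strand) 8.69-fold (7.73 to 9.78) at 205 against 23.6 CPM. Igfbp3, a binding protein of insulin-like growth factors, stood at 225 against 16.3 CPM, 13.8-fold (12.1 to 15.8) lower, and Pycard, the adaptor of inflammasomes, was 13.2-fold (10.6 to 16.5) lower. Also lower were Emid1 (21.2-fold, 15.2 to 30.3), C1qtnf3 (17.5-fold, 13.4 to 23.4), Wfdc1 (16.8-fold, 12.9 to 22.2), Enho (11.6-fold, 9.74 to 14.0), Tril (9.88-fold, 7.23 to 13.7), Cldn1 (9.02-fold, 7.78 to 10.5) and Sdf2l1 (8.66-fold, 7.30 to 10.3). Wnt4 and Cldn1 lead cluster 9, which held 70.2% of wild-type fibroblasts and 0.29% of those labelled knockout, and Csf3 leads cluster 17, with 6.75% and 42.0%. With no replicates, a cluster filled mostly by 1 library may be that library and not a cell type. Other settings moved the log2 ratios of Fosl1 from 2.26 to 3.44, Wnt2 from -4.16 to -5.68 (47 against 2 UMIs, -8.77 to -3.75) and Wfdc1 from -4.07 to -4.75 with thinned cells, and C1qtnf3 from -4.13 to -5.01 as a mean over cells.

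**Figure D3:**
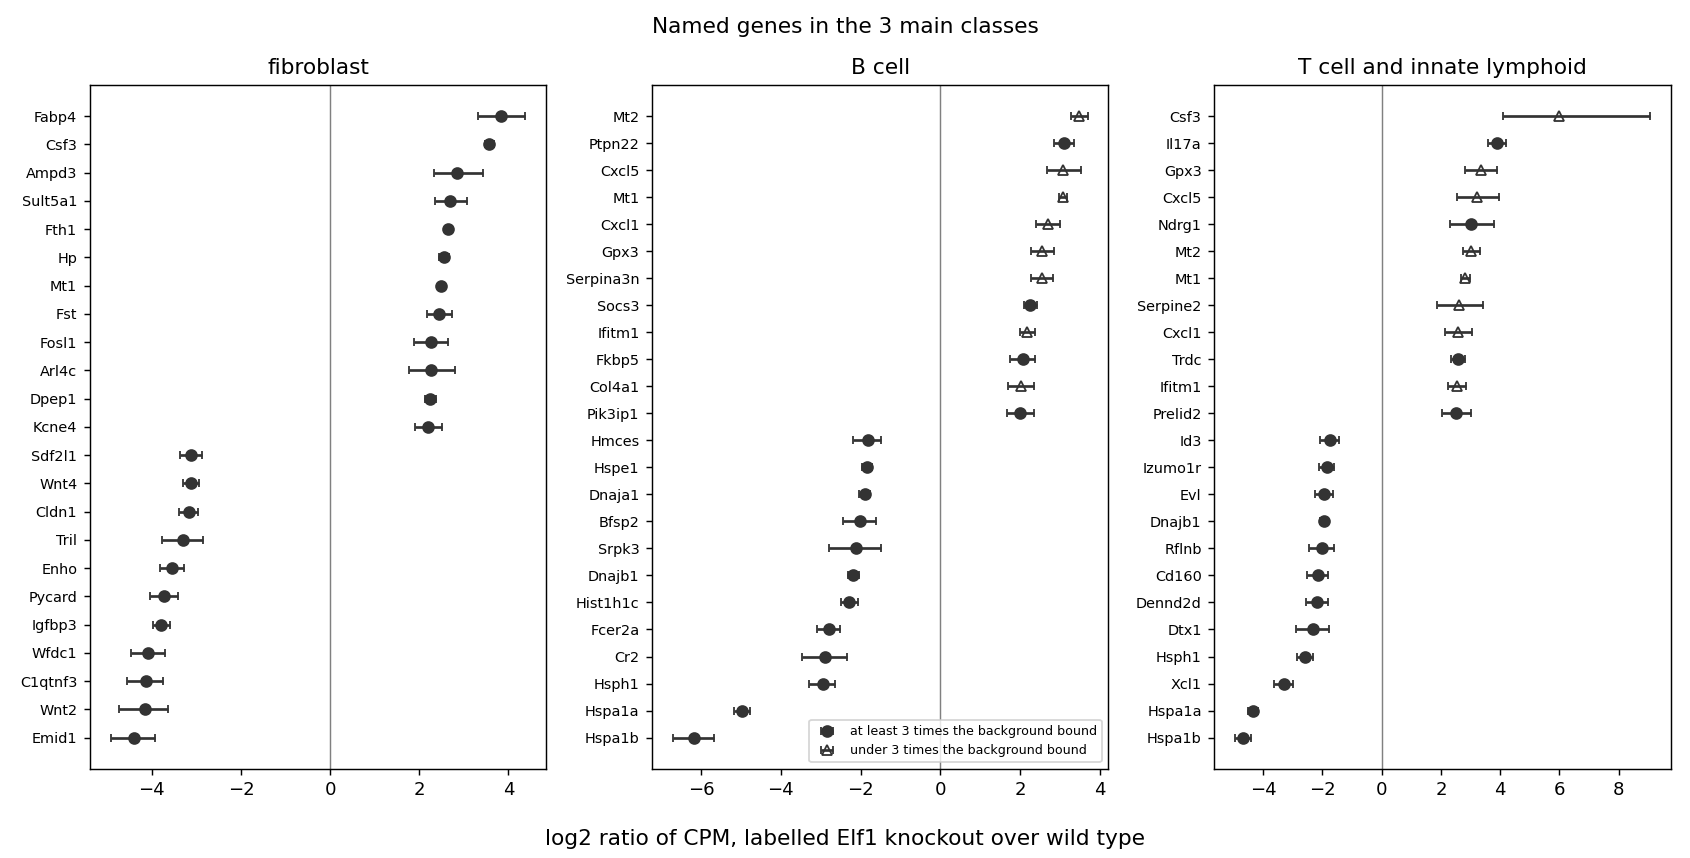
Log2 ratio of labelled knockout over wild type for the genes named in fibroblasts, B cells and T cells, with 95% counting intervals as bars. Filled circles are genes at 3 times the background bound or more and open triangles genes under it, which hold most of the higher genes in B and T cells.

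The gene lists in fibroblasts went in both directions, with the products of inflamed fibroblasts higher in the library labelled knockout and the MHC class II list lower. List values are medians of the log2 ratio over members with at least 50 UMIs, with their counting interval, beside the middle 95% of random lists matched for size and expression (at random), and a count of 0 is taken as 3. The inflammatory fibroblast list had a median of 0.61 (0.56 to 0.66) over 33 of 34 members, against -0.37 to 0.04 for random lists, and 33 members reached 3 times the bound. Lowest were Cxcl12 at -1.41 and Wnt5a at -1.21, and highest Saa3 at 1.93 and Csf3 at 3.57. Cxcl12 and Wnt5a encode a chemokine and a Wnt ligand, and Saa3 an acute-phase protein. The MHC class II list, whose products present antigen to CD4 T cells, had a median of -2.33 (-2.44 to -2.18) over 10 of 12 members, against -0.75 to 0.01 for random lists, and 3 members reached 3 times the bound. Lowest were H2-DMb1 at -3.15 and H2-DMb2 at -3.13, and highest Ctss at -0.52 and H2-Ab1 at 0.35. H2-Ab1 lay at 11.2 times the bound. Over 46 of 46 members of the extracellular matrix list the median was -0.57 (-0.63 to -0.51), with random lists at -0.33 to 0.02 and 46 members at 3 times the bound. Its extremes were Tgfbi at -2.26 and Postn at -2.12 below and Mmp12 at 3.84 and Spp1 at 6.05 above. Mmp12 is a macrophage elastase, and Spp1 the matrix protein osteopontin. Lists of other cells' products were at the extremes too. For the mucus and goblet list, with 10 of 26 members (3 at 0 in 1 library) and 4 at 3 times the bound, the median was -7.01 (-7.01 to -6.27), against -0.78 to 0.00 at random. Members ran from Agr2 (219 against 1 UMIs, 641-fold, 114 to 25413) and Muc2 (131 against 1 UMIs, 383-fold, 67.6 to 15247) to C1galt1 at -0.31 and Creb3l1 at -0.29. Over 12 of 13 members of the immunoglobulin list the median was -2.13 (-2.25 to -1.96), with random lists at -0.62 to 0.07 and 8 members at 3 times the bound. Its extremes were Iglc1 at -5.14 and Iglc3 at -4.24 below and Igkc at 0.95 and Ighg3 at 2.43 above. For the neutrophil granule list, with 22 of 29 members (1 at 0 in 1 library) and 14 at 3 times the bound, the median was 2.26 (1.60 to 2.61), against -0.65 to -0.05 at random. Members ran from Prtn3 at -1.44 and Mmp9 at -1.31 to Chil3 at 4.97 and Ngp (1 against 371 UMIs, 127-fold, 22.6 to 5024). Beside these lists stand 1.51 against 0.0912 UMIs of 19 absorptive and goblet genes per non-epithelial cell, immunoglobulin shares of 13.3% against 9.26% of all UMIs, neutrophil shares of 2.11% against 13.2% of cells and shares of B cells, which carry MHC class II, of 32.8% against 10.7%. Alternatives moved the MHC class II list from -2.33 to -1.39 over members at 3 times the bound, and the mucus list from -7.01 to -0.30 with thinned cells. The immunoglobulin list moved from -2.13 to -0.18 over members at 3 times the bound and to -2.90 with doublets kept. The granule list moved from 2.26 to 0.06 without markers of other classes and to 3.65 with thinned cells. Igkc turned from 0.95 to -2.40 with doublets kept (the farthest of 4 settings that turned it), Prtn3 from -1.44 to 0.61 and Ctss from -0.52 to 0.08 with thinned cells, and C1galt1 from -0.31 to 0.07 and Creb3l1 from -0.29 to 0.09 with TMM scaling.

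B cells carried lower RNA for heat shock proteins and for the receptors Cr2 and Fcer2a in the library labelled knockout, and higher RNA for Ptpn22 and Socs3. The stress-induced chaperones Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238, minus strand) and Hspa1a (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, minus strand) were 71.7-fold (51.3 to 104) and 31.3-fold (27.2 to 36.1) lower, at 1425 against 19.9 CPM and 3726 against 119 CPM. Their partners Hsph1 (7.75-fold, 6.21 to 9.78), Dnajb1 (4.53-fold, 4.11 to 5.004) and Dnaja1 (3.74-fold, 3.40 to 4.12) were lower too, as was the mitochondrial Hspe1 (3.58-fold, 3.28 to 3.91). Cr2, the receptor for complement fragments that lowers the threshold of B cell activation (ENSMUSG00000026616, chromosome 1, 195136811 to 195176716, minus strand), stood at 125 against 16.9 CPM, 7.396-fold (5.10 to 11.1) lower. The low-affinity IgE receptor Fcer2a (ENSMUSG00000005540, chromosome 8, 3681737 to 3694175, minus strand) stood at 414 against 59.6 CPM, 6.95-fold (5.70 to 8.57) lower. The linker histone Hist1h1c was 4.86-fold (4.22 to 5.61) lower, as were Srpk3 (4.31-fold, 2.82 to 6.89), Bfsp2 (4.03-fold, 3.06 to 5.399) and Hmces (3.54-fold, 2.80 to 4.54). Fcer2a leads cluster 3, with 46.7% of wild-type B cells and 4.53% of those labelled knockout, and Bfsp2 leads cluster 13, with 12.1% and 4.24%. Ptpn22, a phosphatase that restrains antigen receptor signalling (ENSMUSG00000027843, chromosome 3, 103859795 to 103912247, plus strand), was 8.53-fold (7.23 to 10.1) higher, at 36.6 against 312 CPM and 43.7 times the background bound. The cytokine signalling inhibitor Socs3 was 4.74-fold (4.23 to 5.33) higher, the glucocorticoid-induced Fkbp5 4.17-fold (3.35 to 5.20) and the PI3 kinase inhibitor Pik3ip1 3.99-fold (3.15 to 5.07). The other 8 genes highest in ratio lay at 1.00 to 1.06 times the background bound, with Mt2 (11.1-fold, 9.59 to 12.9), Cxcl5 (8.46-fold, 6.33 to 11.4), Mt1 (8.44-fold, 7.86 to 9.06), Cxcl1 (6.47-fold, 5.30 to 7.94), Gpx3 (5.85-fold, 4.81 to 7.13), Serpina3n (5.82-fold, 4.81 to 7.06), Ifitm1 (4.52-fold, 3.97 to 5.14) and Col4a1 (4.07-fold, 3.25 to 5.10). The fibroblast product Saa3 shows the size of this background, with a UMI in 13.5% against 73.6% of B cells and in 29.5% against 98.8% of erythroid cells, at median depths of 1410.5 and 1164 UMIs in B cells and 9058.5 and 6888 in erythroid cells. Alternatives moved the log2 ratios of Mt2 from 3.47 to at or below -3.52, Cxcl5 from 3.08 to at or below -1.46, Mt1 from 3.08 to at or below -6.15, Cxcl1 from 2.69 to at or below 0.41, Gpx3 from 2.55 to at or below -3.52, Socs3 from 2.25 to 3.45, Ifitm1 from 2.18 to at or below -3.58, Col4a1 from 2.02 to at or below -0.90, Hspa1b from -6.16 to -7.09 and Hist1h1c from -2.28 to -3.19 with the bound subtracted, Cr2 from -2.89 to -3.65 and Bfsp2 from -2.01 to -1.26 with thinned cells, and Hspe1 from -1.84 to -2.46 and Hmces from -1.82 to -1.05 as a mean over cells.

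By list, heat shock and B cell receptor genes were lower in the B cells of the library labelled knockout. The heat shock list had a median of -1.56 (-1.65 to -1.48) over 15 of 16 members, against -0.33 to 0.18 for random lists, and 14 members reached 3 times the bound. Lowest were Hspa1b at -6.16 and Hspa1a at -4.97, and highest Hsf1 at -0.23 and Bag3 at 0.63. Over 27 of 27 members of the B cell receptor and germinal centre list the median was -0.50 (-0.57 to -0.43), with random lists at -0.24 to 0.12 and 27 members at 3 times the bound. Its extremes were Rgs13 at -2.92 and Cr2 at -2.89 below and Ccr7 at 0.40 and Btk at 0.44 above. Rgs13, a regulator of germinal centre B cells, is among the genes that lead cluster 13, and Ccr7 guides lymphocytes to lymph nodes. For the immunoglobulin list, with 13 of 13 members and 13 at 3 times the bound, the median was 0.03 (-0.05 to 0.07), against -0.35 to 0.19 at random. Members ran from Ighe (90 against 1 UMIs, 28.5-fold, 4.98 to 1137) and Ighg1 at -4.23 to Ighg2c at 1.06 and Ighg2b at 2.07. Lists of other cells' products again lay at the extremes. The neutrophil-attracting list had a median of 2.69 (2.01 to 2.88) over 11 of 19 members, against -0.36 to 0.28 for random lists, and 2 members reached 3 times the bound. Lowest were Ccl3 at -0.38 and Ccl4 at -0.33, and highest Lcn2 at 4.35 and Csf3 at 5.44. Over 21 of 34 members of the inflammatory fibroblast list the median was 2.42 (2.07 to 2.59), with random lists at -0.26 to 0.23 and 0 members at 3 times the bound. Its extremes were Cd44 at 0.54 and Cxcl12 at 0.75 below and Saa3 at 3.94 and Csf3 at 5.44 above. For the mucus and goblet list, with 11 of 26 members (8 at 0 in 1 library) and 2 at 3 times the bound, the median was -3.74 (-3.74 to -2.90), against -0.66 to 0.22 at random. Members ran from Agr2 (294 against 0 UMIs, log2 at or below -4.95 with 0 taken as 3) and Zg16 (246 against 0 UMIs, log2 at or below -4.70 with 0 taken as 3) to Galnt12 at -1.44 and C1galt1 at -0.14. Fibroblasts, the main source of Saa3, carried 37.4 against 185 Saa3 UMIs per cell, and B cells 0.179 against 2.17. Alternatives moved the neutrophil-attracting list from 2.69 to -1.99 and the inflammatory fibroblast list from 2.42 to -2.37 with the bound subtracted, and the immunoglobulin list from 0.03 to -1.54 with separate clustering. The mucus list moved from -3.74 to -0.79 without markers of other classes and to -4.66 over members with at least 200 UMIs. Lcn2 turned from 4.35 to at or below -1.54, Saa3 from 3.94 to at or below -2.15 and Cd44 from 0.54 to -0.17 with the bound subtracted, Cxcl12 from 0.75 to -0.02 with doublets kept, and Ighg2c from 1.06 to -4.90 and Ighg2b from 2.07 to -1.88 with separate clustering.

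T and innate lymphoid cells carried higher RNA for interleukin 17 and the delta chain of the T cell receptor in the library labelled knockout, and lower RNA for heat shock proteins and for the chemokine Xcl1. Il17a, a cytokine that makes epithelial and stromal cells attract neutrophils (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496, plus strand), stood at 51.7 against 760.0 CPM, 14.7-fold (11.9 to 18.3) higher and 355 times the background bound. Trdc, the constant region of the delta chain (ENSMUSG00000104876, chromosome 14, 54142851 to 54148868, plus strand), stood at 89.8 against 533 CPM, 5.94-fold (5.04 to 7.03) higher. The hypoxia-induced Ndrg1 was 8.09-fold (4.97 to 14.0) higher and Prelid2 5.68-fold (4.08 to 8.09). Hspa1b and Hspa1a were 25.4-fold (21.2 to 30.9) and 20.4-fold (18.2 to 22.9) lower, with Hsph1 (6.03-fold, 5.001 to 7.32) and Dnajb1 (3.88-fold, 3.54 to 4.26). Xcl1, which draws cross-presenting dendritic cells, stood at 422 against 42.9 CPM, 9.86-fold (7.94 to 12.4) lower. Cd160, a receptor of natural killer and T cells, was 4.49-fold (3.55 to 5.73) lower, Id3, an inhibitor of E-protein transcription factors, 3.39-fold (2.72 to 4.26), and Izumo1r, the folate receptor 4 of regulatory and follicular T cells, 3.63-fold (3.08 to 4.30). Also lower were Dtx1 (4.99-fold, 3.45 to 7.39), Dennd2d (4.54-fold, 3.51 to 5.93), Rflnb (4.05-fold, 3.03 to 5.48) and Evl (3.88-fold, 3.15 to 4.80). Il17a and Trdc lead cluster 6, which held 9.32% against 24.6% of the class, Xcl1 leads cluster 10, with 36.1% against 23.5%, and Izumo1r cluster 4, with 52.3% against 47.1%. The neutrophil growth factor Csf3 had 2 against 150 UMIs, 63.5-fold (17.3 to 529) higher, at 1.67 times the background bound. Also near the bound, at 1.23 to 1.43 times, were Gpx3 (10.1-fold, 7.10 to 14.9), Cxcl5 (9.22-fold, 5.76 to 15.6), Mt2 (8.09-fold, 6.64 to 9.94), Mt1 (7.06-fold, 6.40 to 7.80), Serpine2 (6.08-fold, 3.64 to 10.8), Cxcl1 (5.995-fold, 4.44 to 8.26) and Ifitm1 (5.77-fold, 4.67 to 7.20). Other settings moved the log2 ratios of Gpx3 from 3.34 to 2.59, Mt2 from 3.02 to 1.79, Mt1 from 2.82 to 1.5005, Serpine2 from 2.603 to 0.25, Cxcl1 from 2.58 to at or above 4.21, Ifitm1 from 2.53 to at or above 5.34 and Id3 from -1.76 to -2.77 with the bound subtracted. Csf3 moved from 5.99 to at or above 4.08 with the bound subtracted and to 6.85 in cells of at least 1000 UMIs.

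The list of T cell receptor and signalling genes, which holds the alpha and beta chains and not Trdc, had a median below 0 in T cells, and activation genes had a median above 0 that lay within the range of random lists. The T cell receptor complex and signalling list had a median of -0.55 (-0.68 to -0.51) over 27 of 27 members, against -0.11 to 0.25 for random lists, and 27 members reached 3 times the bound. Lowest were Cd8a at -1.57 and Themis at -1.30, and highest Cd2 at -0.06 and Cd247 at -0.03. Over 29 of 30 members of the T cell activation and checkpoint list the median was 0.25 (0.14 to 0.35), with random lists at -0.11 to 0.25 and 29 members at 3 times the bound. Its extremes were Cd40lg at -1.41 and Gata3 at -1.08 below and Tnfrsf9 at 1.902 and Il17a at 3.88 above. CD4 T cells held 44.3% against 13.4% of the class, and unnamed T cells may include CD4 cells. Cd40lg is a T cell signal to B cells and Gata3 a regulator of type 2 T cells. For the MHC class II list, with 9 of 12 members and 2 at 3 times the bound, the median was -1.003 (-1.25 to -0.74), against -0.27 to 0.46 at random. Members ran from H2-Ob at -2.28 and H2-Oa at -1.74 to H2-Aa at -0.56 and Ctss at -0.52. The neutrophil-attracting list in T cells had a median of 2.89 (2.55 to 3.17) over 14 of 19 members, against -0.19 to 0.33 for random lists, and 7 members reached 3 times the bound. Lowest were Ccl3 at -1.66 and Ccl4 at -1.52, and highest Lcn2 at 5.83 and Csf3 (2 against 150 UMIs, 63.5-fold, 17.3 to 529). For the inflammatory fibroblast list, with 22 of 34 members and 3 at 3 times the bound, the median was 2.23 (2.004 to 2.56), against -0.18 to 0.34 at random. Members ran from Il6 at -0.84 and Lif at -0.46 to Saa3 at 4.23 and Csf3 (as above). Over 26 of 46 members of the extracellular matrix list the median was 1.62 (1.30 to 1.82), with random lists at -0.16 to 0.32 and 3 members at 3 times the bound. Its extremes were Fbln1 at -0.50 and Timp2 at -0.28 below and Dcn at 3.11 and Mmp3 at 4.14 above. Saa3 gave 0.162 against 3.37 UMIs per T cell, beside 0.386 against 4.61 per erythroid cell. Alternatives moved the neutrophil-attracting list from 2.89 to 1.94 over members at 3 times the bound, and the matrix list from 1.62 to 3.44 with the bound subtracted. The MHC class II list moved from -1.003 to 1.504 with the bound subtracted and to -1.72 with doublets kept. The inflammatory fibroblast list moved from 2.23 to -0.46 over members at 3 times the bound and to 3.28 with the bound subtracted. H2-Aa turned from -0.56 to 1.504 with the bound subtracted.

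Macrophages and monocytes carried higher RNA for Saa3 and Mt2 in the library labelled knockout and lower RNA for MHC class II genes and their regulator Ciita. The acute-phase protein Saa3 (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700, minus strand) stood at 677 against 19448 CPM, 28.7-fold (27.2 to 30.3) higher. The protease inhibitor Serpine2 was 33.3-fold (12.8 to 123) higher, at 2.33 times the background bound, the neutrophil chemokine Cxcl5 17.3-fold (11.5 to 27.5) and the metallothionein Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568, plus strand) 15.03-fold (12.9 to 17.6). Ciita, the master regulator of MHC class II genes (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418, plus strand), stood at 56.0 against 2.23 CPM, 25.1-fold (12.3 to 59.6) lower. The interferon-induced GTPase Gbp8 was 11.3-fold (6.81 to 19.7) lower, Hspa1b 23.4-fold (20.1 to 27.3) and Ppfia4 11.6-fold (7.30 to 19.4). For the MHC class II list, with 10 of 12 members and 10 at 3 times the bound, the median was -2.12 (-2.16 to -2.08), against -0.33 to 0.29 at random. Members ran from Ciita at -4.65 and H2-DMb2 at -2.71 to Ifi30 at -0.95 and Ctss at -0.17. The inflammatory macrophage activation list had a median of 0.43 (0.34 to 0.51) over 35 of 36 members, against -0.20 to 0.11 for random lists, and 35 members reached 3 times the bound. Lowest were Cxcl9 at -2.90 and Cd40 at -1.61, and highest Nos2 at 4.40 and Saa3 at 4.84. Nos2 makes nitric oxide, and Cxcl9 is an interferon-induced T cell chemokine. Over 23 of 25 members of the alternative macrophage activation list the median was -0.14 (-0.27 to 0.02), with random lists at -0.27 to 0.14 and 23 members at 3 times the bound. Its extremes were Ccl24 at -3.33 and Retnla at -3.24 below and Cd163 at 2.46 and Chil3 at 3.83 above. Its interval included 0. Ccl24 is an eosinophil chemokine, Cd163 a scavenger receptor for haemoglobin, and Chil3 a leading gene of cluster 1, which held 58.4% against 62.8% of macrophages. For the inflammatory fibroblast list, with 25 of 34 members and 22 at 3 times the bound, the median was 1.46 (1.34 to 1.73), against -0.24 to 0.14 at random. Members ran from Inhba at -1.43 and Plau at -1.32 to Cxcl13 at 4.41 and Saa3 at 4.84. Over 24 of 29 members of the neutrophil granule list the median was 1.26 (1.02 to 1.45), with random lists at -0.23 to 0.15 and 24 members at 3 times the bound. Its extremes were Cxcr4 at -1.24 and Ncf1 at -0.62 below and Retnlg at 6.46 and Ngp (2 against 474 UMIs, 132-fold, 36.4 to 1095) above. Sub-clustered at resolution 0.5, macrophages split by library, with 192 against 12 and 299 against 23 cells in 2 sub-clusters and 47 against 371 and 21 against 549 in 2 others. Hspa1b, Gbp8, Ppfia4, H2-Eb1 and H2-Aa are among the genes that lead the one of 192 against 12. A further 0 against 17 cells formed a cluster led by Ngp, Retnlg and S100a9, and 1 against 20 a cluster led by Igfbp5, Ccl11 and Dcn among others. For the immunoglobulin list, with 10 of 13 members and 5 at 3 times the bound, the median was -2.01 (-2.19 to -1.87), against -0.35 to 0.25 at random. Members ran from Iglc2 at -3.18 and Ighg1 at -3.16 to Ighg2c at -0.57 and Ighg2b at 2.42. Alternatives moved the log2 ratios of Serpine2 from 5.06 to 4.14 and Hspa1b from -4.55 to -3.94 as a mean over cells, Ppfia4 from -3.54 to -2.52 at resolution 2.0, and Gbp8 from -3.49 to -4.44 (25 against 2 UMIs, -7.56 to -2.44) with thinned cells. Cxcl5 moved from 4.12 to 2.92 as a mean over cells and to 4.73 with doublets kept. Ciita moved from -4.65 to -3.39 at resolution 2.0 and to -5.80 (32 against 1 UMIs, -11.14 to -3.21) with thinned cells. By list, they moved the MHC class II list from -2.12 to -1.47 at resolution 2.0, the immunoglobulin list from -2.01 to -0.77 with thinned cells, and the granule list from 1.26 to -0.20 without markers of other classes. The inflammatory fibroblast list moved from 1.46 to -0.05 without markers of other classes and to 2.07 over members with at least 20 UMIs.

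Smooth muscle cells and pericytes carried higher RNA for Csf3 and the metallothioneins and lower RNA for a potassium channel, a matrix protein and interferon-induced genes in the library labelled knockout. Csf3 stood at 4.50 against 455 CPM, 101-fold (43.2 to 312) higher. Pappa was 36.6-fold (18.5 to 85.0) higher, and the metallothioneins Mt2 23.5-fold (21.4 to 25.9) and Mt1 17.1-fold (16.3 to 17.9). Kcnh2, a potassium channel that sets membrane potential, was 13.3-fold (8.01 to 23.3) lower, the matrix protein Aspn 12.8-fold (10.8 to 15.3), the muscle F-box protein Fbxl22 13.8-fold (10.7 to 17.9) and the dynein chain Dnaic1 17.3-fold (11.7 to 26.5). The NF-kB and TNF response list, genes induced by inflammatory signals, had a median of 1.19 (1.05 to 1.26) over 32 of 39 members, against -0.44 to 0.02 for random lists, and 27 members reached 3 times the bound. Lowest were Cd83 at -2.07 and Ccrl2 at -0.54, and highest Ptx3 (2 against 99 UMIs, 15.6-fold, 4.21 to 131) and Csf3 at 6.66. Cd83 lay at 1.00 times the background bound. Over 23 of 46 members of the type I interferon list the median was -1.17 (-1.52 to -0.998), with random lists at -0.51 to 0.10 and 21 members at 3 times the bound. Its extremes were Ifit3 (48 against 3 UMIs, 50.7-fold, 16.3 to 254) and Ifi27l2a at -2.57 below and Parp14 at 0.22 and Lgals3bp at 0.54 above. For the neutrophil-attracting list, with 10 of 19 members and 7 at 3 times the bound, the median was 1.56 (1.39 to 1.80), against -0.65 to 0.25 at random. Members ran from Il1b at 0.26 and Ccl4 at 0.33 to Lcn2 at 5.68 and Csf3 at 6.66. Over 28 of 34 members of the inflammatory fibroblast list the median was 1.44 (1.24 to 1.53), with random lists at -0.44 to 0.05 and 27 members at 3 times the bound. Its extremes were Tnfaip6 at -0.78 and Plau at -0.71 below and Saa3 at 3.64 and Csf3 at 6.66 above. Saa3 stood at 6.27 against 80.7 UMIs per cell, beside 0.386 against 4.61 in erythroid cells. The fibroblast marker Dcn stood at 12.3 against 68.4 UMIs per smooth muscle cell, beside 56.7 against 139 per fibroblast. Of wild-type smooth muscle cells 70.2% lay in cluster 11, which held 8.75% of those labelled knockout, and 79.4% of the latter lay in cluster 16, against 12.8%. Other settings moved the log2 ratios of Pappa from 5.19 to 3.83 with doublets kept, Dnaic1 from -4.11 to -3.08, Fbxl22 from -3.79 to -3.05 and Aspn from -3.68 to -2.55 at resolution 2.0, and Kcnh2 from -3.74 to -2.98 with thinned cells. Csf3 moved from 6.66 to 5.05 as a mean over cells and to 8.92 with separate clustering. By list, they moved the type I interferon list from -1.17 to -1.94 with thinned cells, and the neutrophil-attracting list from 1.56 to 2.25 at resolution 2.0. Cd83 turned from -2.07 to at or above 0.80 with the bound subtracted.

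Plasma cells, which secrete antibody, had more RNA for the heavy chain of IgM in the library labelled knockout, in a minority of the cells. Ighm, its constant region (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730, minus strand), stood at 69.8 against 2172 CPM, 31.1-fold (27.9 to 34.8) higher, with a UMI in 21.5% against 15.2% of the cells. Csf3 was 15.98-fold (6.53 to 50.8) higher and the membrane protein Tmem119 12.05-fold (4.84 to 38.6), at 2.17 and 2.34 times the background bound, and Hp 15.6-fold (5.77 to 59.5). Gpx2, a glutathione peroxidase of the gut epithelium, had 55 against 1 UMIs, 47.5-fold (8.18 to 1909) lower. The epithelial pentraxin Mptx1 had 53 against 0, a log2 ratio at or below -3.93 with a count of 0 taken as 3. Hspa1b was 18.6-fold (14.3 to 24.7) lower and the endosomal nuclease Pld4 14.9-fold (6.12 to 46.9). The immunoglobulin list had a median of -0.15 (-0.16 to -0.13) over 12 of 13 members, against -0.31 to 0.37 for random lists, and 12 members reached 3 times the bound. Lowest were Iglc3 at -3.88 and Iglc2 at -3.79, and highest Ighg3 at 1.78 and Ighm at 4.96. Iglc2 and Iglc3 encode lambda light chains, and Ighg3 an IgG heavy chain. Over 14 of 16 members of the heat shock list the median was -1.82 (-2.00 to -1.64), with random lists at -0.33 to 0.25 and 14 members at 3 times the bound. Its extremes were Hspa1b at -4.22 and Hspa1a at -3.76 below and Dnajb4 at -0.78 and Hspa4 at -0.22 above. For the B cell receptor and germinal centre list, with 13 of 27 members and 13 at 3 times the bound, the median was -0.40 (-0.69 to -0.16), against -0.42 to 0.27 at random. Members ran from Cd83 at -2.40 and Ms4a1 at -1.96 to Syk at 0.32 and Ebf1 at 0.42. Over 10 of 29 members (2 at 0 in 1 library) of the neutrophil granule list the median was 3.18 (2.995 to 3.39), with random lists at -0.40 to 0.32 and 7 members at 3 times the bound. Its extremes were Ncf4 at -1.46 and Cxcr4 at -0.53 below and Ngp (0 against 72 UMIs, log2 at or above 4.80 with 0 taken as 3) and Retnlg at 5.87 above. For the neutrophil-attracting list, with 10 of 19 members and 4 at 3 times the bound, the median was 1.45 (1.25 to 1.70), against -0.41 to 0.29 at random. Members ran from Il1b at -0.56 and Ccl4 at 0.11 to Csf3 at 3.998 and Lcn2 at 4.17. Over 19 of 34 members of the inflammatory fibroblast list the median was 2.23 (1.95 to 2.48), with random lists at -0.33 to 0.22 and 9 members at 3 times the bound. Its extremes were Cd44 at -0.02 and Cxcl12 at -0.01 below and Saa3 at 3.62 and Csf3 at 3.998 above. Alternatives moved the log2 ratios of Hp from 3.97 to 1.84 in cells of at least 1000 UMIs, Gpx2 from -5.57 to at or below -1.10 with thinned cells, and Pld4 from -3.89 to -1.07 with separate clustering. Csf3 moved from 3.998 to at or above 1.12 with thinned cells and to 5.53 with separate clustering. Tmem119 moved from 3.59 to 2.79 in cells of at least 1000 UMIs and to 4.74 with separate clustering. Mptx1 moved from -3.93 to at or below -1.10 with thinned cells and to at or below -4.83 as a mean over cells. By list, they moved the heat shock list from -1.82 to -1.03, the inflammatory fibroblast list from 2.23 to 3.25 and the B cell receptor list from -0.40 to 0.22 with separate clustering, and the granule list from 3.18 to 1.45 with the bound subtracted. The neutrophil-attracting list moved from 1.45 to 0.22 over members at 3 times the bound and to 3.13 without markers of other classes. Il1b turned from -0.56 to 1.55 as a mean over cells (the farthest of 3 settings that turned it), and Ms4a1 from -1.96 to 0.50 with separate clustering.

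Endothelial cells, which line the vessels, carried higher RNA for Mt1, Mt2 and Cxcl5 and lower RNA for Ifit1 and Ifit3 in the library labelled knockout. Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327, plus strand) stood at 330.0 against 12214 CPM, 37.0-fold (32.8 to 42.0) higher, Mt2 was 24.6-fold (21.0 to 29.0) higher and Cxcl5 15.4-fold (8.28 to 32.6). The matrix protein Spon1, with 2 against 51 UMIs, was 13.7-fold (3.61 to 116) higher. Cysltr1, a receptor of the leukotrienes that make vessels leaky, was 25.1-fold (11.04 to 70.4) lower. Ifit3 and Ifit1, antiviral genes induced by interferon, were 12.3-fold (7.84 to 20.3) and 8.86-fold (5.77 to 14.1) lower, and the apelin receptor Aplnr 11.9-fold (6.86 to 22.1). The neutrophil-attracting list in endothelial cells had a median of 2.10 (1.92 to 2.56) over 10 of 19 members, against -0.34 to 0.29 for random lists, and 9 members reached 3 times the bound. Lowest were Ccl4 at 0.47 and C3 at 1.03, and highest Saa3 at 3.50 and Cxcl5 at 3.95. Over 17 of 36 members of the inflammatory macrophage activation list the median was 1.47 (1.12 to 1.85), with random lists at -0.28 to 0.24 and 14 members at 3 times the bound. Its extremes were Cxcl9 at -2.86 and Cxcl10 at -2.56 below and Saa3 at 3.50 and Cd14 at 3.62 above. Cxcl9 and Cxcl10 are interferon-induced chemokines, and Cd14 is a receptor of bacterial lipopolysaccharide. For the neutrophil granule list, with 11 of 29 members (1 at 0 in 1 library) and 10 at 3 times the bound, the median was 2.65 (2.56 to 2.76), against -0.38 to 0.31 at random. Members ran from Mmp9 at -2.20 to Ngp (0 against 254 UMIs, log2 at or above 5.51 with 0 taken as 3) and Retnlg at 6.31. Over 8 of 13 members of the immunoglobulin list the median was -2.67 (-2.90 to -2.28), with random lists at -0.48 to 0.34 and 3 members at 3 times the bound. Its extremes were Jchain at -3.53 and Iglc2 at -3.10 below and Ighm at -1.73 and Ighg2c at -0.65 above. Other settings moved the log2 ratios of Cxcl5 from 3.95 to 3.20 with doublets kept, Cysltr1 from -4.65 to at or below -2.97, Ifit3 from -3.62 to -5.55 (30 against 1 UMIs, -10.90 to -2.96) and Aplnr from -3.57 to -4.89 (19 against 1 UMIs, -10.27 to -2.24) with thinned cells, and Ifit1 from -3.15 to -2.33 as a mean over cells. Spon1 moved from 3.78 to at or above 1.47 with thinned cells and to 4.76 with separate clustering. By list, they moved the neutrophil-attracting list from 2.10 to 3.04 and the inflammatory activation list from 1.47 to 0.12 without markers of other classes. The immunoglobulin list moved from -2.67 to -1.27 with thinned cells and to -4.90 with the bound subtracted. The granule list moved from 2.65 to 1.05 without markers of other classes and to 4.92 over members with at least 200 UMIs. Mmp9 turned from -2.20 to 2.55 with separate clustering.

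Neutrophils of the library labelled knockout, taken as a class, carried more RNA for granule proteins, which are made early in maturation, and less for interferon-induced genes. The wild-type library held 163 neutrophils with 233676 UMIs, against 1259 with 2619183. Chil3, a chitinase-like lectin of myeloid cells (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564, minus strand), had 1 against 3466 UMIs, 309-fold (55.5 to 12217) higher. Camp, the antimicrobial peptide cathelicidin (ENSMUSG00000038357, chromosome 9, 109847379 to 109849617, minus strand), had 1 against 1789 UMIs, 159.6-fold (28.6 to 6308) higher, and the lipase Lipg 1 against 367, 32.7-fold (5.84 to 1297) higher. The iron-binding granule protein Ltf was 19.9-fold (8.48 to 61.3) higher. The interferon-induced Ifi204 was 7.57-fold (4.46 to 12.6) lower and Gbp2 7.24-fold (4.99 to 10.4), and the lymphocyte cytokine Il15 6.47-fold (3.98 to 10.3). Hspa1a was 9.72-fold (6.99 to 13.5) lower, at 1.00 times the background bound. The neutrophil granule list had a median of 0.30 (0.21 to 0.47) over 26 of 29 members, against -0.52 to 0.03 for random lists, and 26 members reached 3 times the bound. Lowest were Cxcr4 at -2.22 and Csf3r at -1.40, and highest Camp and Chil3 (both as above). Cxcr4 holds neutrophils in the bone marrow, and Csf3r is the receptor for the product of Csf3. Over 24 of 46 members of the type I interferon list the median was -0.94 (-1.19 to -0.80), with random lists at -0.46 to 0.19 and 21 members at 3 times the bound. Its extremes were Slfn5 at -2.92 and Ifi204 at -2.92 below and Zbp1 at -0.25 and Samd9l at -0.15 above. For the heat shock list, with 9 of 16 members and 3 at 3 times the bound, the median was -1.10 (-1.33 to -0.72), against -0.69 to 0.32 at random. Members ran from Hspa1a at -3.28 and Dnajb1 at -1.30 to Dnajb4 at -0.65 and Hspa8 at -0.44. Over 15 of 40 members of the epithelial antimicrobial and injury list the median was 0.48 (0.35 to 0.73), with random lists at -0.61 to 0.21 and 12 members at 3 times the bound. Its extremes were Slpi at -0.90 below and Nos2 (3 against 250 UMIs, 7.43-fold, 2.51 to 36.3) and Saa3 at 3.63 above. For the inflammatory fibroblast list, with 21 of 34 members (1 at 0 in 1 library) and 4 at 3 times the bound, the median was 1.35 (0.93 to 1.61), against -0.39 to 0.34 at random. Members ran from Ptgs2 at -2.33 and Inhba at -1.15 to Saa3 at 3.63 and Grem1 (1 against 151 UMIs, 13.5-fold, 2.38 to 536). Alternatives moved the log2 ratios of Chil3 from 8.27 to at or above 5.47, Camp from 7.32 to at or above 4.22 and Ltf from 4.31 to 2.71 with thinned cells. Lipg moved from 5.03 to at or above 2.55 with thinned cells and to 5.78 as a mean over cells. By list, they moved the heat shock list from -1.10 to 0.02 with the bound subtracted. The inflammatory fibroblast list moved from 1.35 to -1.07 over members at 3 times the bound and to 2.44 with doublets kept. Hspa8 turned from -0.44 to 0.32 with the bound subtracted.

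Dendritic cells, which present antigen to T cells, were few, with 134 against 196 cells. In cells of at least 1000 UMIs they split into a cluster led by Cd209a, Plbd1 and Naaa among others, of 107 against 59 cells, and one led by Ccl22 and Fscn1, of 25 against 102. Clu, the secreted chaperone clusterin, had 1 against 163 UMIs, 157-fold (27.8 to 6231) higher in the library labelled knockout. The neutrophil chemokine Cxcl1 was 23.8-fold (16.1 to 36.7) higher, the serine protease Htra1, with 3 against 72 UMIs, 23.1-fold (7.59 to 115), and Mt2 22.9-fold (13.9 to 40.5), at 2.36 times the background bound. Naaa, an amidase that degrades lipid signals, was 21.8-fold (13.2 to 38.5) lower, the iron regulator Hfe 12.6-fold (5.87 to 32.3), Hspa1b 10.9-fold (8.33 to 14.6) and the brain-type creatine kinase Ckb 10.5-fold (6.08 to 19.8). Over 9 of 19 members of the neutrophil-attracting list the median was 1.82 (1.61 to 2.56), with random lists at -0.53 to 0.56 and 6 members at 3 times the bound. Its extremes were Ccl4 at -0.89 and Il1b at -0.23 below and Cxcl1 at 4.57 and Cxcl3 at 4.80 above. For the epithelial antimicrobial and injury list, with 15 of 40 members and 11 at 3 times the bound, the median was 1.22 (1.01 to 1.62), against -0.45 to 0.45 at random. Members ran from Zbp1 at -2.13 and Ly6a at -1.94 to S100a8 at 4.91 and Clu (as above). S100a8 is a neutrophil protein, and Zbp1 a sensor of viral nucleic acids. The extracellular matrix list in dendritic cells had a median of 2.29 (1.94 to 2.83) over 8 of 46 members, against -0.58 to 0.62 for random lists, and 3 members reached 3 times the bound. Lowest were Tgfbi at 0.43 and Sparc at 1.60, and highest Dcn at 3.30 and Mmp3 at 3.34. For the inflammatory fibroblast list, with 9 of 34 members and 5 at 3 times the bound, the median was 2.23 (1.68 to 3.15), against -0.55 to 0.66 at random. Members ran from Cd44 at -0.42 and Ccl2 at -0.06 to Saa3 at 4.26 and Cxcl1 at 4.57. Alternatives moved the log2 ratios of Clu from 7.29 to at or above 3.59, Mt2 from 4.52 to 6.46 (1 against 117 UMIs, 3.96 to 11.78) and Naaa from -4.44 to -5.07 (76 against 3 UMIs, -7.38 to -3.47) with thinned cells, and Cxcl1 from 4.57 to 3.63, Htra1 from 4.53 to 2.72 and Hfe from -3.66 to at or below -2.60 at resolution 2.0. Ckb moved from -3.40 to -0.87 at resolution 2.0 and to -4.07 (38 against 3 UMIs, -6.41 to -2.42) with thinned cells. By list, they moved the epithelial antimicrobial list from 1.22 to 3.90 at resolution 2.0, and the matrix list from 2.29 to 1.65 at a limit of 10% mitochondrial UMIs. The neutrophil-attracting list moved from 1.82 to 0.97 over members with at least 200 UMIs and to 3.40 with doublets kept. The inflammatory fibroblast list moved from 2.23 to 0.91 over members at 3 times the bound and to 4.26 over members with at least 200 UMIs. Ccl4 turned from -0.89 to 0.17, Il1b from -0.23 to 1.24 and Zbp1 from -2.13 to 0.13 at resolution 2.0.

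**Figure D4:**
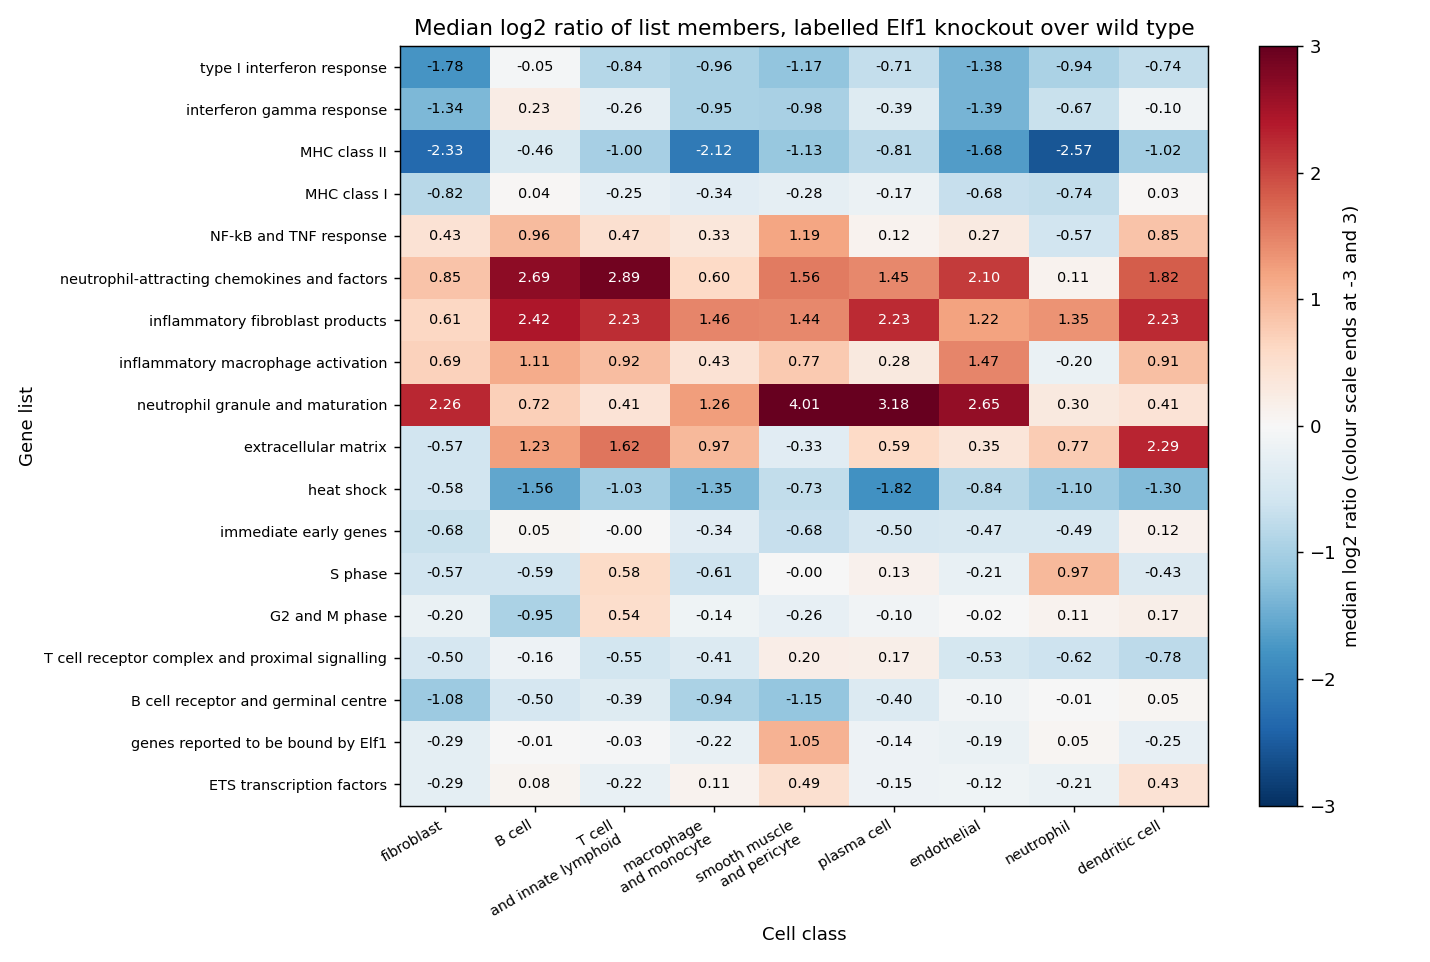
Median log2 ratio of labelled knockout over wild type for 18 gene lists (vertical) in 9 cell classes (horizontal), as colour that ends at -3 and 3 with the value written in each cell. MHC class II stands below 0 in fibroblasts, T cells and macrophages and the inflammatory fibroblast list above 0 in B and T cells. With the background bound subtracted, MHC class II turns in T cells and the inflammatory fibroblast list in B cells.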

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

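The background subtraction and the limit to members at 3 times the background bound were chosen after the results were seen, and all other alternatives before. No paired analysis was possible, with 1 library per group and no mouse of origin per cell. Of 112 alternative values of 13 share ratios of classes, 90 stayed within the counting interval, 22 moved and 0 reversed. Of 3486 alternative log2 ratios of 291 genes in classes, 2992 stayed, 461 moved and 33 reversed, and of 742 list medians 510 stayed, 222 moved and 10 reversed. Of 9 subtype share ratios 6 stayed and 3 moved. Reversed means across 1 (ratios of shares) or 0 (log2 values) where the interval had excluded it, or for lists where the median had lain outside the random range. Values that crossed otherwise, such as the share ratio of glia, count as moved. The cause of these changes was not tested unless stated. The ratio of epithelial shares came to 0.0980 at a limit of 10% mitochondrial UMIs, 0.0987 in cells of at least 1000 UMIs, 0.0880 at resolution 2.0 and 0.0945 with separate clustering. That of B cells came to 0.271 in cells of at least 1000 UMIs. Fibroblasts came to 1.66 with doublets kept and 2.16 at resolution 2.0, and smooth muscle to 2.92 with no mitochondrial limit and 1.002 at resolution 2.0. Among non-epithelial cells the ratios were 0.282 for B cells, 1.59 for fibroblasts and 2.16 for smooth muscle, and without neutrophils 0.367, 2.06 and 2.81, since the whole they are shares of is smaller. The log2 ratio of Elf1 over all cells turned to 0.16 with TMM scaling, and came to -0.15 with totals without mitochondrial, haemoglobin and immunoglobulin genes, -0.19 as a mean over cells and -0.29 with thinned cells. Thinning turned Elf1 in T cells to 0.0251 and, in fibroblasts, Prtn3 to 0.61 and Ctss to 0.0842. TMM scaling shifted all log2 ratios by 0.38 in fibroblasts, 0.36 in neutrophils, 0.31 in smooth muscle, 0.24 over all cells, 0.19 in endothelial cells and 0.15 in macrophages, and so turned C1galt1 and Creb3l1 in fibroblasts to 0.0710 and 0.0909. Subtraction of the background takes off all UMIs in a class that itself sets the bound, which left 0 UMIs in B cells labelled knockout and put Mt2 at or below -3.52, Cxcl5 -1.46, Mt1 -6.15, Gpx3 -3.52, Ifitm1 -3.58, Col4a1 -0.90, Lcn2 -1.54 and Saa3 -2.15, all reversed, with Cd44 at -0.17. Subtraction also turned H2-Aa in T cells to 1.504, Cd83 in smooth muscle to at or above 0.80 and Hspa8 in neutrophils to 0.32. By list it turned the neutrophil-attracting and inflammatory fibroblast medians of B cells to -1.99 and -2.37, MHC class II in T cells to 1.504, and heat shock and inflammatory fibroblast in neutrophils to 0.0239 and -0.23. Over members at 3 times the bound the neutrophil-attracting median was -0.36 in B cells, and the inflammatory fibroblast median -0.46 in T cells and -1.07 in neutrophils. Without markers of other classes, macrophages had -0.0535 for inflammatory fibroblast products and -0.20 for neutrophil granules. Igkc in fibroblasts turned to -0.37 with no mitochondrial limit, -2.40 with doublets kept, -0.15 at resolution 2.0 and -0.56 with separate clustering, and Cxcl12 in B cells to -0.0179 with doublets kept. Separate clustering also turned Ighg2c and Ighg2b in B cells to -4.90 and -1.88, Il1b and Ms4a1 in plasma cells to 0.0449 and 0.50 and Mmp9 in endothelial cells to 2.55. Il1b in plasma cells was 1.55 as a mean over cells and 0.0912 with thinned cells, and resolution 2.0 turned Ccl4, Il1b and Zbp1 in dendritic cells to 0.17, 1.24 and 0.13. Of these, Prtn3, Mmp9 and Zbp1 rest on 1 to 3 UMIs in 1 library. Some alternatives gave no value. No B cell member of the inflammatory fibroblast list reached 3 times the bound, and too few members were left without markers of other classes for immunoglobulin in fibroblasts, macrophages and endothelial cells, granules in plasma cells and neutrophil-attracting factors in dendritic cells. Erythroid cells had no named cluster in at least 1 library at resolution 0.5 or with separate clustering, nor mast cells with the latter. Thinning left too few members for the neutrophil-attracting and inflammatory fibroblast lists in plasma cells and for the matrix list in dendritic cells, where 200 UMIs per member left too few as well. Elf1 over all cells, Hspa1a in neutrophils, Cxcl12 in B cells and Ccl4 in smooth muscle have no value with the background subtracted, Naaa in dendritic cells none at resolution 2.0 and Tmem119 in plasma cells none when thinned. Depth limits genes with few UMIs, and thinning left 3 or fewer in 1 library for some named genes, such as Chil3 and Camp in neutrophils, which then are bounds or rest on those UMIs.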

Other observations

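The tests of explanations in this part were chosen after the results they concern had been seen. Genes induced by interferons, the cytokines of antiviral and antibacterial defence, had lower list medians in the library labelled knockout in most classes (random gives the range of random lists). The type I interferon median was -1.78 (-1.90 to -1.62, random -0.53 to -0.18) in fibroblasts, -1.38 (-1.65 to -1.26, random -0.30 to 0.12) in endothelial cells, -0.96 (-1.14 to -0.85, random -0.25 to 0.08) in macrophages and -0.84 (-0.98 to -0.68, random -0.12 to 0.28) in T cells. B cells were the exception, at -0.05 (-0.25 to 0.03, random -0.27 to 0.19). The interferon gamma median was -1.39 (-1.46 to -1.14, random -0.23 to 0.12) in endothelial cells, -1.34 (-1.46 to -1.21, random -0.45 to -0.10) in fibroblasts, -0.98 (-1.11 to -0.84, random -0.44 to 0.06) in smooth muscle, -0.95 (-1.06 to -0.87, random -0.23 to 0.10) in macrophages, -0.67 (-0.91 to -0.32, random -0.59 to 0.18) in neutrophils and -0.26 (-0.35 to -0.15, random -0.08 to 0.26) in T cells, against 0.23 (0.04 to 0.30, random -0.22 to 0.17) in B cells. Ifng itself, made mostly by T cells, stood at 349 against 173 CPM in those cells. The cytotoxic effector list in T cells had a median of -0.65 (-0.84 to -0.50, random -0.14 to 0.28). Genes of the S phase had medians of -0.59 (-0.66 to -0.44, random -0.19 to 0.14) in B cells and 0.58 (0.44 to 0.68, random -0.10 to 0.28) in T cells, and those of the G2 and M phases -0.95 (-1.09 to -0.85, random -0.20 to 0.10) and 0.54 (0.44 to 0.63, random -0.08 to 0.25). B cell cluster 13, led by Pclaf, Mki67 and Top2a among others, held 12.1% against 4.24% of B cells. Genes reported to be bound by Elf1 had medians of -0.29 (-0.57 to -0.13, random -0.79 to -0.01) in fibroblasts, -0.01 (-0.20 to 0.04, random -0.34 to 0.26) in B cells and -0.03 (-0.09 to 0.29, random -0.21 to 0.40) in T cells. Each lay within the range of random lists, and the TMM shift of 0.38 in fibroblasts turns the first above 0. These lists were not run under the other settings, beyond the shifts by TMM scaling.

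Fibroblasts held most UMIs of several secreted factors in both libraries, and within fibroblasts some of these were higher and others lower in the library labelled knockout. In fibroblasts Csf3 stood at 134 against 1594 CPM, Cxcl5 at 1169.7 against 3596 CPM, Cxcl1 at 1149 against 3433 CPM, the matrix protease Mmp3 at 2188 against 7805 CPM, the cytokine Il11 at 1014 against 2163 CPM and the B cell chemokine Cxcl13 at 3052 against 5624 CPM. Lower were the chemokine Cxcl12, at 2429 against 917 CPM, the macrophage growth factor Csf1, at 115 against 59.4 CPM, and Wnt5a, at 146 against 63.5 CPM. T cells held most of the UMIs of Il22, a cytokine that acts on epithelium, at 636 against 1748 CPM within them. Hbegf and Il18, mostly epithelial in the wild-type library, stood at 314 against 18.7 and 81.9 against 9.86 CPM over all cells.

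The presence of Elf1 RNA in the library labelled knockout has explanations that the data treat differently. Free RNA is argued against by 1.01 Elf1 UMIs per T cell over 0.0361 per erythroid cell in that library, a ratio of 28.0 (9.54 to 136). Erythroid cells did not hold less of the fibroblast products Saa3 and Dcn there. Saa3 gave 4.61 UMIs per erythroid cell and 3.37 per T cell, and Dcn 2.43 and 1.99. Transcripts from parts of Elf1 outside the deleted sequence and a mislabelled or wild-type sample cannot be told apart, since the deleted part is not given in the sources used here, and the ratio of 0.94 over all cells could come from either.

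The few epithelial cells in the library labelled knockout were weighed in the same way. The limit on mitochondrial UMIs is argued against by a share ratio of 0.045 without it, and epithelial cells broken in the suspension by 1.51 against 0.0912 absorptive and goblet UMIs per non-epithelial cell, a ratio of 0.06 (0.0562 to 0.0648), where breakage would have raised them. A loss of all epithelial cells alike is argued against by the enteroendocrine cells, at 0.311% against 0.579% of kept cells, a ratio of 1.86 (1.13 to 3.15), though with 24 and 55 cells. A difference in colitis severity or genotype may underlie the ratio of 0.012 (0.0065 to 0.0194) for the other epithelial cells, 1043 against 15 (in cells of at least 1000 UMIs this moves up, with epithelial clusters not led by Chgb and Chga of 665 against 41 and 118 against 0 cells), but with 1 library per group these cannot be told apart from each other, or from a difference in dissociation, which was not tested.

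Heat shock genes had lower medians in the library labelled knockout in 9 of 9 compared classes, from -1.82 in plasma cells to -0.58 in fibroblasts, though that of neutrophils turned to 0.02 with the background bound subtracted. Free RNA is argued against by the spread of Hspa1a in the wild-type library, from 18.1 UMIs per plasma cell to 0.442 per neutrophil, a ratio of 41.1. A difference in handling of the suspensions before lysis may have induced these genes, and immediate early genes, which handling also induces, had medians below 0 in 7 of 9 classes, from -0.68 in fibroblasts and smooth muscle to -0.00270 in T cells, which is close to 0, but stood at 0.05 in B cells and 0.12 in dendritic cells, where handling as the cause was set to need medians below 0 in all classes. A difference in colitis severity or genotype could give the median Hspa1a log2 ratio of -3.08 over the classes as well. Handling, severity and genotype cannot be told apart, because each is confounded with the library.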
